A study of Mus musculus with 2 samples.

How the data were processed

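The series holds 10x Genomics 5′ single-cell RNA libraries from mouse yolk sac of the B6 strain, 1 wild-type (WT) and 1 Baf155 CKO. Per the labels, equal numbers of E9.5 and E10.5 embryos were mixed per genotype, dissociated with 0.25% collagenase, frozen, sorted for live Ter119-negative cells and sequenced on an Illumina HiSeq. The number of embryos, the Cre driver and the deleted exon are not given in the sources used here. The labels call the material nuclei while the protocol describes live cells, and the stage of a single cell is not known. The submitters' processing notes name Cell Ranger with GRCm38 and Seurat. The deposited matrices hold UMI counts per gene and barcode, which were whole numbers, for 33456 genes with the same gene table in both libraries, and 97.6% of the gene IDs were found in GENCODE release 21 for the mouse. A symbol was shared by more than 1 gene ID in 180 cases, and 8 genes of the gene lists and 2 marker genes were not in the files.

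The WT library had 815 barcodes and 24538853 UMIs (6054 to 114332 per barcode), and the CKO library 865 barcodes and 27314411 UMIs (6328 to 96471 per barcode), with median genes of 4378 and 4353 and median mitochondrial shares of 1.91% and 2.20%. Only 1 barcode was shared. The share that 3 cells make, the floor for a class with 0 cells, was 0.383% in WT and 0.357% in CKO. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet at an expected rate of 1% (3 WT and 6 CKO barcodes, 0.368% and 0.694%), and 28 WT and 18 CKO barcodes were over the mitochondrial limit, leaving 784 and 841 cells.

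Both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes (seen in at least 3 cells) were scaled to a maximum of 10, and Leiden clustering at resolution 1.0 was run on 15 neighbours in 30 principal components. Globin, mitochondrial, Xist and Y-linked genes were not used as variable genes. Haematopoietic clusters were clustered again. A cluster was named when 3 markers of a class were seen in at least 25% of its cells and were at least 2-fold above the other cells with 5 CPM added, and its top 10 genes held no more markers of another class. Counting markers over the merged lists of a class was chosen after seeing the data. The progenitor-like class merged the erythromyeloid progenitor and granulocyte-monocyte lists, and the stromal-like class the mesenchyme, smooth muscle and mesothelium lists. A cluster with fewer markers, or with a median depth under the library median divided by 3 and no marker among its top genes, would stay unnamed. The unnamed clusters c6 and c10 passed stromal markers, but their top 10 genes held more markers of another class (Plac1 and Fst). Work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9, with seed 0.

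The 15 marker lists were summed over each library, WT then CKO, in CPM: visceral endoderm 1979 and 78.7, endothelium 366 and 444, mesenchyme 2336 and 3003, smooth muscle 956 and 765, mesothelium 122 and 168, erythromyeloid progenitor 238 and 272, erythroid 72113 and 97909, megakaryocyte 182 and 855, macrophage 284 and 59.4, granulocyte-monocyte 242 and 141, mast cell 4.27 and 1.04, trophoblast 18.8 and 16.9, parietal endoderm 58.6 and 143, neural 19.6 and 16.8, and lymphocyte 13.4 and 3.94.

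With 1 library per genotype no test between genotypes was possible, and none was made. Shares have exact binomial 95% intervals, and CPM values exact Poisson intervals. CPM ratios of CKO over WT within a class use the sum of counts over its cells and a conditional binomial interval. UMIs of 1 cell are not independent of each other, so these intervals are narrower than the spread between embryos. Classes with at least 20 cells per library were compared: progenitor-like, erythroid-like, endothelium-like and stromal-like, with 9443891 and 6929033, 5484177 and 9413815, 755611 and 808215, and 5739336 and 4998543 UMIs. Genes needed 20 UMIs over both libraries (10796, 8803, 6712 and 10781 genes). The median log2 ratio over these genes was 0.05, 0.19, -0.03 and -0.04. Named genes were those with the largest ratios among genes with at least 100 UMIs over both libraries and seen in at least 10% of the cells of the library with the higher level, leaving out ribosomal protein, mitochondrial, predicted (Gm and Rik) and sex-linked genes: 12 higher and 12 lower in progenitor-like and endothelium-like cells, 6 and 6 in the others, of which most are given. The rule also names BAF genes, globins and the most abundant list members, of which examples are given; other list members were picked as examples after seeing the data. A gene with 0 UMIs in 1 library is given as at least N-fold against a floor of 3 counts, which is not a 95% limit.

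The 24 gene lists were fixed before the data were examined. A list's shift is the median log2 ratio with 0.5 CPM added, over at least 5 members, set against 10000 random lists of genes matched in 20 bins of level. Of 84 list and class pairs, 51 lay beyond 95% of random lists, where lists of unrelated genes would give 4.2. Members of a list may vary together, so 4.2 is not the number expected without an effect of genotype. Cell cycle shares count cells with Mki67 or Top2a after thinning to 11472 UMIs, the 10th percentile, leaving out shallower cells (progenitor-like 18 WT and 7 CKO, erythroid-like 14 and 21, endothelium-like 22 and 2, stromal-like 31 and 10).

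The steps were tested on simulated data in which the count sums of each class were drawn from Poisson distributions with known ratios. No spread between cells or embryos was simulated. Coverage near 95% thus follows from this setting and does not show the coverage for the real data. Intervals of unchanged genes held the truth in 95.6%, 95.8%, 96.2% and 96.1% of genes in the 4 classes. Direction was right in 100% of the genes set to a ratio of 0.25, 0.5, 2 or 4, and a ratio of 4 gave medians of 4.06, 4.07, 3.95 and 3.97. Lists of 20 genes with no change lay inside random lists in 94.0%, 95.0%, 94.5% and 95.5% of cases.

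Alternatives fixed in advance changed the cell filter (no filter, or at least 1000 genes and at most 5% mitochondrial), the doublets, the Leiden resolution (0.5 and 2.0), the genes or cells used to cluster, the scaling, the weight of cells, the count minimum (5 and 100 UMIs), the added CPM (1 and 5) and the thinning. Added after seeing data were a naming rule with 3 markers of a single list, leaving out the CKO cells of h0, h3, h4 and h5, and comparing only Xist-positive or only Y-positive cells. In comparisons by sex, Xist-positive cells held Xist and no Y-linked UMIs, and Y-positive cells held Y-linked and no Xist UMIs. Megakaryocyte-like, macrophage-like, endoderm-like and unnamed cells were left out of the comparison of all genes for lack of cells in 1 library or of a name. A few genes and lists are still given for macrophage-like cells, whose 11 CKO cells were below the minimum of 20.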

Results

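The yolk sac makes the early blood of the mouse embryo. Primitive erythroid cells carry embryonic globins, and erythromyeloid progenitors bud from haemogenic endothelium and give rise to definitive erythroid cells, megakaryocytes and macrophages. Smarcc1 encodes Baf155, a core subunit of the BAF (SWI/SNF) chromatin remodelling complex. The series holds 1 wild-type (WT) and 1 Baf155 CKO library of live Ter119-negative yolk sac cells, each from E9.5 and E10.5 embryos mixed in equal numbers. There was 1 library per genotype, no replicate and no test, so the intervals below are 95% intervals that cover counting error only, and a difference between embryos, sorts or libraries cannot be separated from one of genotype.

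After filtering, 784 WT and 841 CKO cells remained, with medians of 27249 and 27882 UMIs per barcode before filtering. Smarcc1 (ENSMUSG00000032481, chromosome 9, 110117708 to 110240178, plus strand, GRCm38) stood at 94.9 CPM (91.0 to 98.8) over all WT cells and 24.0 CPM (22.2 to 25.9) over all CKO cells, a ratio of 0.253 (0.232 to 0.276). Which part of the gene was deleted is not given in the sources used here, so RNA of a deleted allele may still be counted. At least 1 Smarcc1 UMI was seen in 83.3% of WT and 33.1% of CKO cells. The ratio was 0.0905 (0.0320 to 0.208) in endothelium-like, 0.131 (0.0997 to 0.171) in erythroid-like, 0.318 (0.277 to 0.364) in progenitor-like and 0.326 (0.274 to 0.387) in stromal-like cells. It was 0.558 (0.332 to 0.895) in macrophage-like cells, and the 4 CKO endoderm-like cells lay above WT, at 124 CPM (65.9 to 212; 13 UMIs) against 42.3 CPM (29.6 to 58.6). CKO cells of the erythroid clusters h8, h9 and h10, which held no WT cells, had 4.95 CPM (3.59 to 6.64), and the progenitor cluster h7, also without WT cells, had 10.9 CPM (8.15 to 14.4). CKO cells in the progenitor-like clusters h0 and h5, which both libraries filled, kept 92.6 CPM (80.5 to 106) against 133 CPM (124 to 143) in WT cells of the same clusters. The CKO cells of h3 kept 48.0 CPM and those of the macrophage cluster h4 kept 44.9 CPM. With the CKO cells of h0, h3, h4 and h5 left out, the ratio over all cells was 0.174 (0.156 to 0.194), and it was 0.139 within Xist-positive and 0.403 within Y-positive cells. In the progenitor-like class the CKO level was 9.88 CPM in Xist-positive and 57.3 CPM in Y-positive cells.

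**Figure D1:**
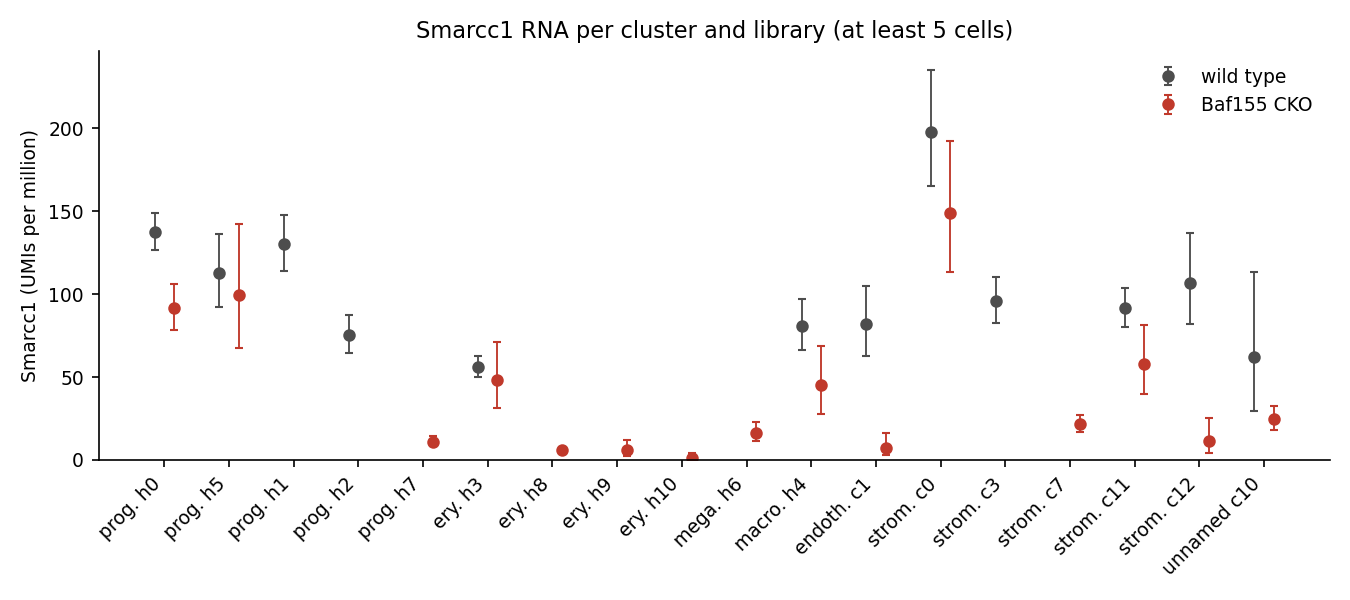
Smarcc1 level in CPM in blood, endothelium-like and stromal-like clusters and in the unnamed c10, as points with 95% counting intervals. WT and CKO libraries are shown where they have at least 5 cells in a cluster. The unnamed c6 and the endoderm-like c9 and c13 are not shown. CKO cells of h8, h9 and h10 together stand at 4.95 CPM and those of h7 at 10.9 CPM, while CKO cells of h0 and h5 together stand at 92.6 CPM.

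The list of BAF genes, which includes Smarcc1, showed no common shift. Its median log2 ratio was -0.00 in progenitor-like, 0.13 in erythroid-like, -0.05 in endothelium-like and -0.21 in stromal-like cells, each inside 95% of random gene lists. Smarcc2, the paralogue of Smarcc1, had ratios of 1.30, 1.5, 0.990 and 0.938 in these 4 classes. The ATPase gene Smarca4 had 1.37, 1.25, 0.881 and 0.978, Smarcb1, another core subunit, had 0.859, 0.822, 1.16 and 0.831, and Smarce1 1.02, 1.08, 0.966 and 0.977. Actl6a had 0.933, 1.19, 1.11 and 0.815, Pbrm1 0.858, 1.10, 0.955 and 0.734, and Arid1a 1.47, 1.46, 1.08 and 0.929.

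The balance of blood cell types in the yolk sac reflects how progenitors leave for the erythroid, megakaryocyte and macrophage lineages. Because Ter119-positive erythroid cells were sorted away, the erythroid share is that of cells still negative for this marker. Among all kept cells, progenitor-like cells made up 30.5% (27.3 to 33.8) of WT and 20.5% (17.8 to 23.3) of CKO cells, and erythroid-like cells 19.6% (16.9 to 22.6) and 30.1% (27.0 to 33.3). The progenitor-like class includes clusters that passed granulocyte-monocyte markers. Megakaryocyte-like cells were 1 of the WT cells and 79 of the CKO cells, 0.128% (0.00323 to 0.709) and 9.39% (7.51 to 11.6). Macrophage-like cells were 5.48% (4.0 to 7.32) of WT and 1.31% (0.655 to 2.33) of CKO cells. Of the haematopoietic cells alone, progenitor-like cells were 54.7% (49.9 to 59.4) and 33.4% (29.3 to 37.7), and erythroid-like cells 35.2% (30.8 to 39.9) and 49.1% (44.7 to 53.5). Megakaryocyte-like cells were 0.229% and 15.3% (12.3 to 18.7) of haematopoietic cells, and macrophage-like cells 9.84% (7.21 to 13) and 2.14% (1.07 to 3.79). The named non-blood classes were lower in the CKO library in this setting: endothelium-like 6.38% (4.77 to 8.32) and 3.57% (2.42 to 5.05), endoderm-like 4.21% (2.91 to 5.86) and 0.476% (0.130 to 1.21), stromal-like 30.9% (27.6 to 34.2) and 20.7% (18.0 to 23.6). Clusters without a name held 2.81% of WT and 14.0% of CKO cells. They were closest to stromal cells and passed stromal markers, so the lower stromal-like share does not show fewer stromal cells. With WT cells clustered alone, stromal-like cells were 34.4% of WT and 35.1% of CKO cells.

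Classes were filled by different clusters in the libraries. The progenitor-like class held h0 (104 WT and 34 CKO cells), h1 (55 and 0), h2 (55 and 0), h5 (25 and 7) and h7 (0 and 131). Of the markers of this class, h0 passed Cd34 and the granulocyte-monocyte markers Mpo and Prtn3. The erythroid-like class held h3 (154 and 14), h8 (0 and 147), h9 (0 and 37) and h10 (0 and 55). A cluster from 1 library may be that library rather than a cell type. Several shares turned on the settings. With doublets kept, the progenitor-like difference was 0.539 points in place of -10.0. Only 3 WT and 6 CKO barcodes were added, so the change came with clustering and naming the cells again rather than from doublets alone. With 3 markers of a single list needed, the progenitor-like difference was -0.810 points (17.2% of WT and 16.4% of CKO cells). No single list gave h0 3 markers, so h0 lost its name under this rule. The lower progenitor-like share thus rests largely on naming h0 by merged lists, chosen after seeing the data. At stricter cell filters or Leiden resolution 2.0, CKO cells joined the endothelium-like class and its difference was 6.76 or 7.06 points in place of -2.81. With WT cells clustered alone, the stromal-like difference was 0.639 points in place of -10.2. Within Y-positive cells progenitor-like cells were 28.1% of WT and 27.5% of CKO cells, whereas within Xist-positive cells they were 35.2% and 13.3%. The macrophage-like difference stayed between -4.30 and -2.64 points under every alternative, and the megakaryocyte-like share was higher in the CKO library under all of them. How few WT cells were megakaryocyte-like depended on clustering the libraries together: with WT cells clustered alone, they were 3.44% of WT and 7.02% of CKO cells, and 7.30% and 16.0% of haematopoietic cells.

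**Figure D2:**
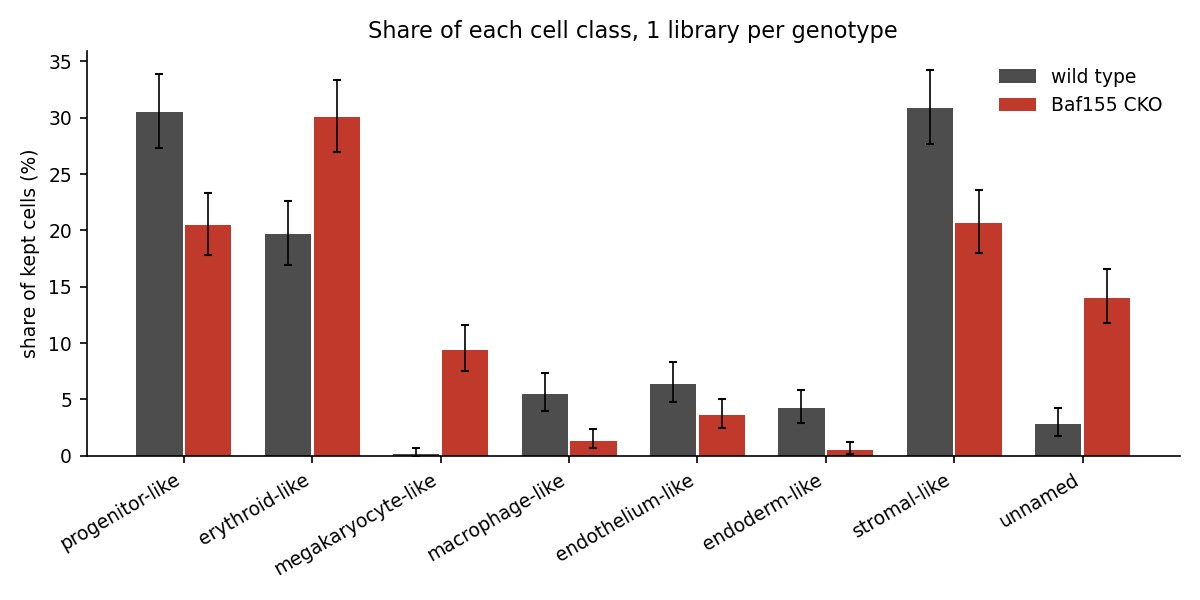
Share of kept cells in each class, in percent, as bars for the WT and CKO libraries with 95% counting intervals. Megakaryocyte-like cells are 0.128% of WT and 9.39% of CKO cells, and macrophage-like cells 5.48% and 1.31%.

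Erythromyeloid progenitors express Runx1, Kit and Cd34 once they have left the endothelium, shut down the arterial and pan-endothelial programme, and open the erythroid or the myeloid one. Klf1, Gata1 and Epor mark the step to the erythroid lineage. Cells that hold endothelial and blood genes together stand at the transition between the 2 fates. The progenitor-like classes (239 WT and 172 CKO cells, medians 41100 and 37814 UMIs) differed in 18 of 24 gene lists beyond 95% of random lists, where lists of unrelated genes would give 1.2.

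Genes of the erythroid step were lower in the CKO progenitor-like cells. Klf1 (ENSMUSG00000054191), the erythroid master regulator, stood at 43.0 CPM in WT and 1.88 CPM in CKO cells, 22.9-fold lower (13.2 to 43.4). Car1, a carbonic anhydrase of definitive erythroid progenitors, was 20.8-fold lower (10.4 to 48.8), the TGF-beta family ligand Gdf3 17.0-fold and the amino acid transporter Slc38a5 15.7-fold. Car1 was not lost from the CKO library. It had 227 WT and 8 CKO UMIs in progenitor-like cells but 2 WT and 638 CKO UMIs in erythroid-like cells. The iron reductase gene Steap3 was 5.48-fold lower, the adhesion gene Icam4 6.29-fold and the mucin gene Muc13 5.44-fold. Other genes with the largest ratios were RP23-362B7.1 (16.1-fold lower), the troponin gene Tnni3 (7.40-fold), Smim5 (6.03-fold), the tetraspanin gene Tspan15 (5.89-fold) and the activation marker gene Cd69 (5.49-fold). Of 18 erythroid regulators and membrane genes 12 were lower and 6 higher, with a median of -1.24 (random lists -0.17 to 0.43): Gata1 had a ratio of 0.195 (0.143 to 0.262), the erythropoietin receptor gene Epor 0.189 (0.116 to 0.293) and Ermap 0.0649 (0.0173 to 0.172). Nfe2, Gfi1b and Tal1, which progenitors share with the megakaryocyte lineage, had 1.23, 1.19 and 1.03. The haem list had a median of -0.25 (7 higher, 12 lower), with Cpox at 0.346 and Alad at 0.529, while the ferritin genes Ftl1 and Fth1 had 1.39 and 1.14. It lay inside random lists within Xist-positive cells (-0.06) and with the CKO cells of h0 and h5 left out (-0.18). The WT cells that carry these genes were mostly those of h2, where Klf1 stood at 172 CPM and Gata1 at 117 CPM, and no CKO cell fell in that cluster. The list median ranged up to -0.50 with 5 CPM added and down to -1.94 at Leiden resolution 2.0. The log2 ratio of Klf1 was -3.05 within Xist-positive and -6.03 within Y-positive cells.

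Endothelial genes were higher in the same cells. The arterial transcription factor gene Sox17 (ENSMUSG00000025902) stood at 2.65 CPM in WT and 71.3 CPM in CKO cells, a ratio of 26.9 (18.0 to 42.0). Gja4, an arterial gap junction gene, had 21.6, and Ecscr, an endothelial surface regulator, stood at 20.1 CPM in WT and 267 CPM in CKO cells, 13.3 (11.4 to 15.5). The collagen gene Col26a1 had 0 WT and 126 CKO UMIs, in 36.6% of CKO cells, at least 57.2-fold higher. The imprinted gene Mest had a ratio of 23.7 (19.6 to 29.0), the growth factor gene Igf1 9.38 (7.79 to 11.4) and the matrix gene Ltbp1 13.4. The surface genes Cd200 and Lilrb4 had ratios of 18.9 and 17.3, and the LIM-domain gene Lmo1 12.9. The arterial list had a median of 1.99 (6 higher, 1 lower), with Vegfc at 5.17 and Notch1 at 0.697. The pan-endothelial list had 1.14 (21 higher, 2 lower), with Tie1 at 4.32, Esam at 3.84, Cdh5 at 3.05 and Kdr at 2.78, while the abundant Egfl7 and Fli1 had 1.38 each, and Plvap and Icam2 0.857 and 0.917. The venous list had a median of 0.70, with Lyve1 at 3.02 and Nrp2 at 1.14, but turned to -0.80 at the stricter cell filter. Haemogenic genes had a median of 0.08, inside random lists, with Gata2 at 1.07, Cbfb at 1.21, Itga4 at 0.273 and Spn at 0.344. At Leiden resolution 2.0, the log2 ratio of Sox17 was 1.74 in place of 4.75 and that of Mest 2.39 in place of 4.57. The pan-endothelial median was 0.25, inside random lists, at the stricter cell filter. Cluster h7 stood highest among the progenitor clusters, with Sox17 at 106 CPM and Ecscr at 389 CPM. It passed 6 erythromyeloid progenitor markers (Kit, Gata2, Cd34, Myb, Mycn and Ikzf2) and Mpo, and 6 endothelium markers (Pecam1, Cdh5, Kdr, Esam, Tie1 and Egfl7). Its top genes included Sox17 and Ecscr and none of these progenitor or endothelium markers, so its class name was a close call. Since h7 held 131 of the 172 CKO cells of the class, the higher endothelial genes rest largely on that name.

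Most myeloid and progenitor regulators were higher. The progenitor list had a median of 0.26 (17 higher, 5 lower), with Cd34 at 1.94 (1.83 to 2.05), Runx1 at 1.34 (1.22 to 1.47), Hhex at 1.49, Lyl1 at 0.862, Mycn at 2.94 and Hoxa9 at 0.208. The 6 erythromyeloid progenitor markers that h7 passed, Cd34 and Mycn among them, are all members of this list. Its shift is therefore partly set by how h7 was named. The myeloid list had 0.47 (17 higher, 5 lower): the master regulator Spi1 had 1.01 (0.950 to 1.07), Fcer1g 1.42, Coro1a 0.907, Id2 7.44 and Lyz2 2.36, while Irf8 and Cebpa had 0.640 and 0.690. The list lay inside random lists within Xist-positive cells (0.24) and with the CKO cells of h0 and h5 left out (0.27). Granule proteins had -0.19, inside random lists, with Prtn3 at 0.663, Mpo at 1.32 and Srgn at 1.72. Macrophage function genes had 0.38 (11 higher, 6 lower), with the chemokine gene Ccl3 at 5.42, Ctsd at 0.902 and Apoe at 0.595, but -0.81 within Xist-positive cells. With the CKO cells of h0 and h5 left out, they had 0.29, inside random lists. The megakaryocyte list had 0.26, inside random lists, with Clec1b at 6.83, Pf4 at 3.84, Plek at 1.88 and Nrgn at 0.706.

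Targets of p53 were higher in CKO progenitor-like cells, with a median of 0.91 (19 higher, 3 lower). The cell cycle inhibitor gene Cdkn1a had a ratio of 3.99 (3.47 to 4.60), and the death genes Pmaip1 and Bbc3 4.17 (3.58 to 4.86) and 3.66 (3.18 to 4.23), while Bax and Ei24 had 0.889 and 1.52. The stress genes Chac1 and Trib3 had 10.1 and 9.97, which came mostly from the CKO cells of h0 and h5: without them the log2 ratios were 0.60 and 1.60 in place of 3.34 and 3.32. Interferon response genes had a median of 0.86 (16 higher, 2 lower), with Bst2 at 1.77 and Ifitm3 at 0.703, and matrix genes 0.85 (15 higher, 4 lower), with Hapln1 at 3.32, Sparc at 2.22 and Col1a1 at 0.895. Glycolysis and hypoxia genes had 0.31 (20 higher, 8 lower), with Gapdh at 1.32 and Ldha at 0.896, but -0.17 within Xist-positive cells. HOX genes had 0.83 (5 higher, 2 lower), with Hoxb4 at 1.84 and Hoxb5 at 6.93. Genes of growth and division were lower. MYC and ribosome genes had -0.35 (3 higher, 22 lower), with Myc at 0.317 and the nucleolar genes Ncl and Npm1 at 0.680 and 0.838. S phase genes had -0.24 (8 higher, 34 lower), with Rrm2 at 0.453 and Nasp at 0.762, and G2 and M genes -0.20 (11 higher, 41 lower), with Hmgb2 at 0.711 and Tubb4b at 0.558. Immediate early stress genes had -0.15, inside random lists, with Hspa1a at 0.245, Hsp90aa1 at 0.670 and Hspa8 at 0.993.

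Erythroid RNA was also seen in these cells, and how much of it was free RNA was not tested. Hbb-y, an embryonic globin, stood at 187 CPM in WT and 1136 CPM in CKO progenitor-like cells, beside 165 and 2017 CPM in stromal-like cells, and the globin list had a median of 1.36. Hbb-bh1 UMIs per Hba-x UMI were 3.65 (3.34 to 3.99) in WT and 1.23 (1.17 to 1.28) in CKO progenitor-like cells, against 1.61 (1.39 to 1.86) and 1.06 (1.02 to 1.10) in stromal-like cells. Slc4a1 had a ratio of 15.9 (3 WT UMIs, 5.01 to 80.8). Endoderm genes had a median of -1.0 (2 higher, 9 lower), beside endoderm markers at 1979 CPM over the whole WT and 78.7 CPM over the whole CKO library.

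**Figure D3:**
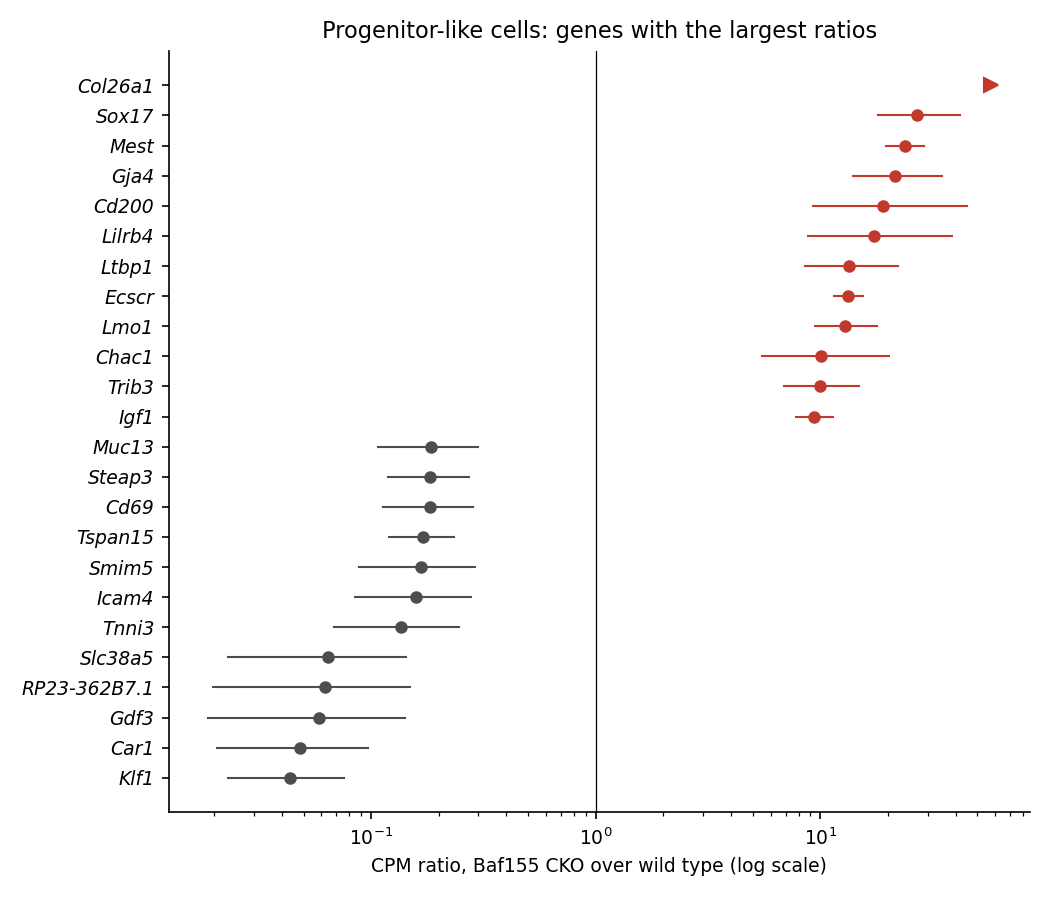
CPM ratio of CKO over WT progenitor-like cells (log scale) for the 12 higher and 12 lower genes with the largest ratios, as points with 95% counting intervals, and for Col26a1 as an arrow at its lower bound of 57.2. Sox17 lies at 26.9, and Klf1, the lowest, at 0.0436.

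Erythroid cells of the yolk sac at E9.5 and E10.5 are mostly primitive erythroblasts, which carry Hbb-y, Hbb-bh1 and Hba-x, while definitive erythroid cells from erythromyeloid progenitors carry Car1 and adult globins. Both divide as they fill with haemoglobin and lose progenitor genes on the way. The erythroid-like class (154 WT and 253 CKO cells, medians 33015.5 and 35270 UMIs) had a median log2 ratio of 0.19 over all measured genes, against which the lists are read, and 12 of 18 lists lay beyond 95% of random lists.

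Embryonic globin levels were close in the 2 libraries, and most adult globins were lower in the CKO library. Hbb-y stood at 139103 CPM in WT and 112748 CPM in CKO cells (0.811), Hbb-bh1 had a ratio of 0.980 and Hba-x 1.04. The adult genes Hba-a1 and Hba-a2 had 0.651 and 0.537, and Hbb-bt and Hbb-bs 0.187 and 1.00, though reads of these near-identical paralogue pairs are hard to assign. The globin list had a median of -0.06, inside random lists. Erythroid regulators and membrane genes had 0.54 (17 higher, 4 lower): Nfe2 had 2.38 (2.05 to 2.77), the anion exchanger gene Slc4a1 1.51 and Klf1 1.09 (1.02 to 1.17), while the blood group gene Rhd had 0.420. Haem genes had 0.21, inside random lists, with the ferritin gene Fth1 at 0.576.

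Of the genes higher in CKO erythroid-like cells, Car1 (ENSMUSG00000027556) had the largest ratio, though it was seen in only 11.5% of CKO cells. It had 2 WT UMIs, 0.365 CPM, and 67.8 CPM in CKO cells, a ratio of 186 (51.2 to 1538), and stood at 328 CPM in the CKO cluster h9. In progenitor-like cells Car1 was lower in the CKO library (227 WT and 8 CKO UMIs). The platelet chemokine gene Pf4 had 1 WT UMI and 15.6 CPM in CKO cells, 85.6 (15.1 to 3405). The haem oxygenase gene Hmox1 had 17.9, the butyrophilin gene Btn1a1 17.4, the piRNA pathway gene Tdrkh 14.6 and the cytoskeletal gene Schip1 11.6. Progenitor regulators had a median of 0.93 (12 higher, 1 lower), with Lyl1 at 1.98, Lmo2 at 1.94, Tal1 at 1.91 and Gfi1b at 1.61, but 0.19 within Y-positive cells. The megakaryocyte list had 1.71 (8 higher, 2 lower), with Gp9 at 7.05, Itgb3 at 0.706 and Itga2b at 0.808, but 0.02 within Y-positive cells. The CKO library also held more megakaryocyte-like cells (79 against 1) and more megakaryocyte marker RNA (855 against 182 CPM), so free RNA in this list and in Pf4 was not excluded. Genes lower in CKO cells were the complement response gene Rgcc (15.7-fold), the steroid enzyme gene Hsd3b6 (14.0-fold), the fatty acid binding gene Fabp5 (12.2-fold, 10.9 to 13.8), Arhgdig (9.70-fold), the cytokine receptor gene Csf2rb (9.58-fold, 7.67 to 12.1) and Hesx1 (7.65-fold).

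Genes of division and glycolysis were higher in the CKO erythroid-like cells. S phase genes had a median of 0.43 (38 higher, 4 lower), with Pcna at 2.49, Mcm5 at 2.38 and the abundant Nasp at 1.32, and G2 and M genes 0.32 (41 higher, 10 lower), with Top2a at 1.67 and Hmgb2 at 1.32. Hypoxia and glycolysis genes had 0.63 (24 higher, 3 lower), with Bnip3 at 3.40, Eno1 at 2.28, Gapdh at 1.53 and Ldha at 1.02. Interferon genes had 1.04 (6 higher, 0 lower), with Bst2 at 2.65 and Isg15 at 1.12, haemogenic genes 0.63 (9 higher, 1 lower) and myeloid regulators 0.81, the last 2 turning to -0.13 within Y-positive and to -0.13 within Xist-positive cells. Immediate early stress genes had -0.13 (10 higher, 11 lower), and 0.24 within Xist-positive cells. Targets of p53 had 0.27, with Ccng1 near 2-fold and Bax at 0.813, and MYC genes 0.10, both inside random lists. Matrix genes had 1.54 (11 higher, 2 lower), where Col1a1 stood at 15.8 CPM in CKO cells beside 2377 CPM in CKO stromal-like cells. Endoderm genes had -1.96 (1 higher, 4 lower), with Ttr at 0.0583 and Apoa1 at 0.0760.

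Yolk sac endothelium forms the vascular plexus and holds the haemogenic cells from which progenitors bud. The endothelium-like class was the cluster c1, with 50 WT and 30 CKO cells. Median depths differed, 13094.5 UMIs in WT and 24109.5 in CKO cells, and 8 of 20 lists lay beyond 95% of random lists.

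Within the endothelium-like class, endothelial identity genes were similar in both libraries. The class was formed on expression and named by endothelium markers, among them Ramp2, Plvap, Cdh5 and Kdr. CKO cells with changed endothelial genes could fall outside it. The similarity is therefore partly set by how the class was formed and does not show that endothelial identity was unchanged. The pan-endothelial, arterial and venous lists had medians of -0.10, -0.17 and -0.01, all inside random lists, with Ramp2 at 1.09, Plvap at 0.918, Cdh5 at 0.779, Kdr at 0.863, the arterial gene Sox17 at 1.69 and the venous genes Lyve1 and Emcn at 0.991 and 0.400. The imprinted cell cycle inhibitor gene Cdkn1c (ENSMUSG00000037664) stood at 1538 CPM in WT and 55.7 CPM in CKO cells, 27.6-fold lower (20.5 to 38.1), and was seen in 82.0% and 60.0% of cells. Dlk1, an imprinted Notch ligand gene, was 16.8-fold lower (10.7 to 28.0) by UMIs but seen in 22.0% of WT and 46.7% of CKO cells, so its WT RNA came from few cells. By UMIs, Basp1 was lower 4.55-fold, the interferon-induced gene Ifitm3 4.32-fold, the RNA-binding gene Hnrnpa0 4.30-fold, the protease gene Adamts5 3.70-fold and the growth factor gene Mdk, seen in 36% of WT and 60.0% of CKO cells, 3.46-fold. Plac1, Ppp4r2, Fam167b, Acbd3 and Cmtm8 were 3.69-fold, 3.66-fold, 3.59-fold, 3.49-fold and 3.48-fold lower. The interferon list had -1.63 (0 higher, 6 lower), with Rtp4 at 0.181 and Rsad2 at 0.0693, and matrix genes had -0.31 (3 higher, 11 lower), with Fn1 at 0.437 and Col4a1 at 0.801.

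Stress and p53 genes were higher. Targets of p53 had a median of 0.77 (12 higher, 4 lower), with Cdkn1a at 6.47 (3.51 to 13), Ccng1 at 5.06, Plk2 at 1.98 and Bax at 1.16. Immediate early genes had 0.48 (21 higher, 2 lower), with Ier3 at 5.05, Fos at 4.67, Zfp36 at 3.66 and Hspa8 at 1.17. Hypoxia genes had 0.40 (19 higher, 4 lower), S phase genes 0.29 (26 higher, 12 lower) and MYC genes 0.31 (18 higher, 6 lower), while G2 and M genes had -0.06, inside random lists. The histone gene Hist1h2ap had 7.21 (4.95 to 10.8), the lipid chaperone gene Fabp4 5.45 and the heat shock gene Hspb1 3.11. Atp5g2, Pgk1 and Gadd45g had 4.41, 3.39 and 3.31. Globins were higher too, and free RNA was not tested for in this class, with Hbb-y at 246 and 1302 CPM, Hba-x at a ratio of 6.80, Hba-a1 at 4.97, Hbb-bh1 at 4.51 and a list median of 2.29. Hbb-y was seen in 100% of CKO cells of this class and of the stromal-like class. The globin ratios are thus not read as expression by endothelial cells. The class changed with the settings: at the stricter filter and at Leiden resolution 2.0, CKO cells joined it, 20 and 21 lists lay beyond random, the pan-endothelial median was -1.14 and -1.34, and the log2 ratio of Fabp4 was 0.43 and 0.35 in place of 2.45.

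Stromal cells of the yolk sac are mesoderm-derived mesenchyme, smooth muscle and mesothelium, patterned along the body axis by HOX genes. The stromal-like class (242 WT and 174 CKO cells, medians 22870.5 and 26583.5 UMIs) held c3 (82 WT and 1 CKO cells), c11 (102 and 18) and c7 (0 and 116), with c0 (25 and 16) and c12 (33 and 23) shared, and 13 of 22 lists lay beyond 95% of random lists.

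HOX genes were lower in the CKO stromal-like cells, with a median of -1.18 (2 higher, 18 lower). Hoxb9 had a ratio of 0.0209 (1 CKO UMI, 0.000519 to 0.121), Hoxb7 0.255 (0.144 to 0.429), Hoxb4 0.323, Hoxb2 0.603, Hoxc6 0.648 and the most abundant, Hoxc8, 0.716, while Hoxc9 and Hoxc10 had 1.12 and 3.77. Hoxa9 had 42 WT and 0 CKO UMIs and was at least 12.2-fold lower, and Hoxa7 had 28 and 0, at least 8.13-fold lower. The HOX median was -0.62 with at least 100 UMIs, -0.53 under the single-list naming rule, -0.69 within Xist-positive and -1.67 within Y-positive cells. Other lower genes were the potassium channel gene Kcnk3 (10.4-fold, 5.76 to 20.6), Ifitm10 (6.82-fold), the mesenchymal transcription factor gene Twist1 (5.92-fold, 3.69 to 10.0), the peroxisomal gene Acox3 (4.99-fold), Tox3 (3.67-fold) and Rasl11a (3.64-fold).

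Immediate early stress genes were higher in these cells, with a median of 0.58 (19 higher, 6 lower), Zfp36 at 5.70, Fosb at 4.17, Btg2 at 3.77 and Hspa1a at 0.696. The list had 0.04 within Xist-positive and 1.05 within Y-positive cells. The metallothionein gene Mt2 stood at 8.19 CPM in WT and 97.0 CPM in CKO cells, 11.8 (8.77 to 16.3), p53 targets had 0.33 (15 higher, 7 lower), hypoxia genes 0.24 (22 higher, 6 lower) and matrix genes 0.12 (17 higher, 12 lower), with Col1a1 at 0.940 and Lum at 0.748. G2 and M genes had -0.37 (6 higher, 46 lower) and S phase genes -0.21 (9 higher, 33 lower), with Hmgb2 at 0.780 and Nasp at 0.761. Haem genes had 0.17, but -0.14 within Xist-positive cells, and pan-endothelial genes 0.36 (8 higher, 5 lower), but -0.10 within Y-positive cells. Erythroid RNA was higher too, and how much of it was free RNA was not tested, with Hbb-y at 165 and 2017 CPM, Hba-x at a ratio of 18.3, Hba-a1 at 13.5 and Hbb-bh1 at 12.1. At least 3 erythroid markers were seen in 100% of all kept CKO cells and 84.2% of WT cells. These ratios are thus not read as globin expression by stromal cells. The globin, erythroid and megakaryocyte lists had 3.58, 1.58 and 1.13. The macrophage list had 0.49, with Apoe at 1.73 and Ctsd at 1.47, although macrophage markers were lower over the whole CKO library (59.4 against 284 CPM).

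Proliferating yolk sac cells express Mki67 and Top2a. In cells thinned to 11472 UMIs, at least 1 of these UMIs was seen in 92.3% (88.0 to 95.5) of WT and 81.8% (75.1 to 87.4) of CKO progenitor-like cells, and in 82.5% (76.6 to 87.3) and 72.6% (65.1 to 79.2) of stromal-like cells. The erythroid-like values were 92.9% (87.3 to 96.5) and 94.8% (91.1 to 97.3), and both endothelium-like values were 78.6% (59.0 to 91.7). Without thinning, the progenitor-like values were 97.49% and 91.3%. Across alternatives, the difference stayed between -13.7 and -6.21 points in progenitor-like cells and between -13.9 and -6.73 points in stromal-like cells. In endothelium-like cells it was 1.45 to 12.7 points across alternatives against 0 points in the setting used, and in erythroid-like cells -0.423 to 7.05 points.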

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

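Of the weighing below, the mixing, library-wide effect, carried-over cells, random escape, free globin and doublet comparisons were chosen after the result was seen, and the others were written before their values were computed.

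For 9 of 24 gene lists the median log2 ratio had opposite signs in 2 or more classes, each beyond 95% of random lists, and these differences between classes were not tested. Erythroid regulators had -1.24 in progenitor-like, 0.54 in erythroid-like and 1.58 in stromal-like cells, and haem genes -0.25 in progenitor-like and 0.17 in stromal-like cells. How much of the erythroid RNA in stromal-like cells was free RNA was not tested. Within Xist-positive progenitor-like cells haem genes had -0.06, inside random lists. S phase genes had -0.24 in progenitor-like, 0.43 in erythroid-like, 0.29 in endothelium-like and -0.21 in stromal-like cells, and G2 and M genes -0.20, 0.32 and -0.37 in progenitor-like, erythroid-like and stromal-like cells. Interferon genes had 0.86 in progenitor-like, 1.04 in erythroid-like and -1.63 in endothelium-like cells. Matrix genes had 0.85, 1.54, -0.31 and 0.12 in progenitor-like, erythroid-like, endothelium-like and stromal-like cells. HOX genes had 0.83 in progenitor-like and -1.18 in stromal-like cells, and MYC genes -0.35 in progenitor-like and 0.31 in endothelium-like cells. Immediate early stress genes had -0.13, 0.48 and 0.58 in erythroid-like, endothelium-like and stromal-like cells.

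Endothelial genes were higher in CKO progenitor-like cells, most of which were in h7, whose class name was a close call. Mixing with cells like the CKO endothelium-like cells of c1, or with their RNA, could make up at most 3.17% by Cldn5, the largest of 4 limits. Ecscr needs at least 54.0%, so mixing with c1-like cells was ruled out as the whole source. Endothelial cells of another type, low in Plvap, Ramp2, Cldn5 and Lyve1, were not tested for. The test of an effect on all cells of the library written beforehand, on macrophage-like cells, decided nothing (0.45 over 5 genes in 11 CKO cells, random lists -0.70 to 0.69), and stromal-like cells had 0.36. The median of -0.59 in CKO cells of h0 and h5, put in its place afterwards, cannot decide it either. These clusters were formed on expression, so CKO cells with higher endothelial genes could fall outside them. An effect on all cells of the library was left open. Unequal sex did not account for the pattern, as the smaller median within 1 sex was 0.95. Loss of Smarcc1 cannot be told apart from other causes, since h0 and h5 keep Smarcc1 but were formed on expression.

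CKO cells of h0, h3, h4 and h5, blood clusters that hold WT cells, kept Smarcc1, at 78.6 CPM in 66 cells against 8.19 CPM in 449 other haematopoietic CKO cells. Cells carried over from the WT library after droplets were made would keep its Hbb-y level, 174 CPM, but Hbb-y stood at 1176 CPM in h0, h4 and h5, while WT cells mixed in earlier were not tested for. Deletion missed at random in blood cells of every embryo was not seen, as 15.2% of them held Xist UMIs, with or without Y-linked UMIs, against 59.9% of the others. Stromal CKO cells went the other way: c0 kept 149 CPM with 68.8% and c11 57.8 CPM with 66.7% Xist-positive cells, and shared clusters c1 and c12 had 7.42 and 11.6 CPM. Male embryos without the deletion cannot be told apart from other causes, with Smarcc1 in Y-positive against Xist-positive CKO cells at 8.98 (5.49 to 13.9) and 6.18 CPM (4.42 to 8.42) in erythroid-like, 7.29 and 6.20 in endothelium-like and 34.6 and 35.3 in stromal-like cells, but 57.3 and 9.88 in progenitor-like and 29.8 (17.9 to 46.5) and 9.51 (4.35 to 18.1) in megakaryocyte-like cells.

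Some megakaryocyte-like CKO cells held embryonic globin RNA, with Hbb-bh1 at 5143 CPM pooled but 769 CPM in the median cell, beside 1036 CPM in CKO stromal-like cells. Hbb-bh1 per Hba-x was 5.14 (4.90 to 5.40) in them against 1.06 (1.02 to 1.10) in stromal-like, 1.18 (1.04 to 1.35) in endothelium-like and 1.20 (1.01 to 1.43) in macrophage-like CKO cells, which speaks against free RNA if the globin RNA of those classes is free. Doublets with erythroid cells would give 0.875 to 1.21, below the lower limit of 4.90. WT progenitor cluster h2 had 6.35 (5.58 to 7.25). The top 10 of 79 cells held 70.6% of the Hbb-bh1 UMIs, so these ratios describe few cells.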

How the results depend on the processing

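Across 184 results, 2517 alternative values were computed: 2200 stayed the same, 305 moved and 12 reversed. Values below are CKO minus WT in points for shares, log2 medians for lists, and ratios for Smarcc1. Apart from h0 losing its name under the single-list rule, the causes of these changes were not tested. Named genes kept at least a 2-fold difference in 22 to 24 of 24 progenitor-like, 10 to 12 of 12 erythroid-like, 21 to 24 of 24 endothelium-like and 12 of 12 stromal-like cases.

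Doublets kept: progenitor-like share 0.539 (19.1% and 19.6%) in place of -10.0, and of haematopoietic cells -10.8 in place of -21.3. The haematopoietic erythroid-like share was 5.10 in place of 13.9. In progenitor-like cells, erythroid regulators had -1.86 and pan-endothelial genes 1.44, in place of -1.24 and 1.14.

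At least 1000 genes and at most 5% mitochondrial: megakaryocyte-like share 5.34 in place of 9.27 (haematopoietic 11.1 in place of 15.1), endothelium-like 6.76 in place of -2.81, endoderm-like -2.13 in place of -3.73. In progenitor-like cells, myeloid regulators had 0.82, p53 targets 0.67, venous genes -0.80 and pan-endothelial genes 0.25, in place of 0.47, 0.91, 0.70 and 1.14. In endothelium-like cells, 20 lists lay beyond random in place of 8.

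Leiden resolution 2.0: endothelium-like share 7.06. In progenitor-like cells, erythroid regulators had -1.94, myeloid regulators 0.80, p53 targets 0.47 and pan-endothelial genes 0.64. In endothelium-like cells, 21 lists lay beyond random.

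WT cells clustered alone: megakaryocyte-like share 3.57 (3.44% of WT and 7.02% of CKO cells in place of 0.128% and 9.39%), haematopoietic 8.69 (7.30% and 16.0%), stromal-like 0.639 in place of -10.2, haematopoietic erythroid-like 26.7. Clustered without 5667 genes that differ between libraries: megakaryocyte-like 4.51 (haematopoietic 7.34).

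At least 100 UMIs: erythroid regulators in progenitor-like cells -0.86 and HOX genes in stromal-like cells -0.62 in place of -1.18. With 5 CPM added: erythroid regulators -0.50, p53 targets 0.57 and pan-endothelial genes 0.83 in progenitor-like cells, and HOX genes -0.61 in stromal-like cells.

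The other settings were chosen after seeing the data. With 3 markers of a single list, the progenitor-like share was -0.810 (haematopoietic -11.9) and the haematopoietic erythroid-like share 6.35. Erythroid regulators then had -1.66, p53 targets 1.24 and pan-endothelial genes 2.06 in progenitor-like cells, and HOX genes -0.53 in stromal-like cells. Without the Smarcc1-keeping cells, Smarcc1 was 0.174 in place of 0.253, and erythroid regulators and pan-endothelial genes had -1.66 and 1.48 in progenitor-like cells.

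Xist-positive cells only: shares were progenitor-like -21.9, erythroid-like 22.9 in place of 10.4 and endothelium-like -0.471, and of haematopoietic cells progenitor-like -39.0 and erythroid-like 31.1. Smarcc1 was 0.139. Reversed lists were macrophage function (-0.81 in place of 0.38) and hypoxia (-0.17 in place of 0.31) in progenitor-like cells, myeloid regulators (-0.13 in place of 0.81) and stress (0.24 in place of -0.13) in erythroid-like cells, and haem (-0.14 in place of 0.17) in stromal-like cells. Globins in erythroid-like cells had -0.34 in place of -0.06, and HOX genes in stromal-like cells -0.69.

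Y-positive cells only: shares were progenitor-like -0.642, erythroid-like 2.21, megakaryocyte-like 7.25 and stromal-like -17.0, and of haematopoietic cells progenitor-like -5.97 and erythroid-like 0.980. Smarcc1 was 0.403. Reversed lists were haemogenic genes (-0.13 in place of 0.63) in erythroid-like and pan-endothelial genes (-0.10 in place of 0.36) in stromal-like cells. Targets of p53 had 0.50 in progenitor-like and HOX genes -1.67 in stromal-like cells.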

Other observations

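The comparisons of the CKO cells in h0 and h5, of macrophage-like cells and of sex within clusters were chosen after the result was seen.

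The megakaryocyte-like cluster h6 held 79 CKO cells and 1 WT cell and passed 8 megakaryocyte markers, the progenitor markers Gata2, Cd34 and Mycn, and the endothelial markers Kdr, Esam and Tie1. In its CKO cells Gata1 stood at 105 CPM. The gap junction gene Gja4 stood at 106 CPM (91.6 to 121), Ecscr at 63.5 CPM and Sox17 at 4.10 CPM, against 81.7 (63.2 to 104), 385 and 170 CPM in CKO endothelium-like cells. Gja4 was thus not accompanied by Sox17 at the endothelial level, and 1 WT cell gives no WT level to compare. The p53 targets Bbc3 and Cdkn1a stood at 157 and 81.5 CPM, Smarcc1 at 16.4 CPM (11.2 to 23.1), and 71.2% of the thinned cells held Mki67 or Top2a UMIs. Macrophage-like cells of the CKO library were 11, under the minimum of 20 for a compared class, against 43 in WT. Their Cdkn1a ratio was 16.8 (8.50 to 36.9) and that of Bbc3 5.40 (2.56 to 12.0), while macrophage function genes had a median of -1.59 (4 higher, 19 lower).

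CKO cells of h0 and h5, which kept Smarcc1, also had higher Cdkn1a, at a ratio of 2.54 (2.10 to 3.07), Bbc3 at 2.59 and Pmaip1 at 3.01. Plk2 had 0.503 (0.339 to 0.729), Mdm2 1.05 and Ccng1 1.22, and the p53 list had 0.06 (10 higher, 9 lower), inside random lists. Their immediate early stress list had -1.31 (2 higher, 21 lower).

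The CKO progenitor-like cells might be held between endothelial and blood fates, with Runx1 and Spi1 kept and Klf1 low. This is a hypothesis: mixing with c1-like cells allows at most 3.17%, but endothelial cells of another type were not tested for. Most of the CKO progenitor-like cells were in h7, whose class name was a close call. The pan-endothelial list had 0.25 at the stricter cell filter, and a library difference in stage or embryo was not tested. Replicate libraries of genotyped embryos of 1 stage would test it: the hypothesis fails if CKO progenitors without Smarcc1 do not have Sox17 and Ecscr above and Klf1 below WT in each.

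Pgk1, an X-linked glycolytic gene, was higher in every compared class, with ratios of 3.05, 7.0, 3.39 and 3.57 in progenitor-like, erythroid-like, endothelium-like and stromal-like cells. Whether these counts include RNA from a PGK promoter cassette in the targeted allele was not tested, so they are not read as the gene's own level. Rrp1b, a ribosome biogenesis gene, had 0.404, 0.714, 0.935 and 0.397 in the same classes. The CKO erythroid clusters differed in sex, with 81.0% of h8, 97.3% of h9 and 29.1% of h10 cells holding Xist UMIs.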
